A study of Mus musculus with 2 samples.

How the data were processed

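Single-cell RNA was measured in 2 libraries of mouse stomach metaplastic organoids, replicate 1 (IM15) and replicate 2 (IM17) of a single group. Per the labels' protocols, epithelial cells were dissociated, enriched for viable cells with magnetic beads, captured in inDrop droplets, amplified with the linear method of CEL-Seq and sequenced on a NextSeq500. Reads were placed on the mouse genome build GRCm38, per the submitters' processing notes. The aligner, the UMI counter, the annotation and the rule by which barcodes were filtered are not given in the sources used here.

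The deposited matrices hold log2 values: each is log2 of a cell's CPM plus 1, as read from the values themselves. Raised back and less 1, the values of every barcode sum to 1000000, and within a barcode 100% of values are whole multiples of a common step within a tolerance of 0.001. Whole UMIs per gene and barcode were recovered on that basis and used throughout. The deposited matrices list 19112 gene symbols without gene identifiers, of which 18358 (96.1%) match a name in the reference gene table, and 0 are mitochondrial. Positions of named genes come from the GENCODE annotation of the same build, matched by symbol, for 273 of 278 genes.

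A total of 9251 barcodes with 3010995 UMIs (IM15) and 5411 barcodes with 1788142 UMIs (IM17) were used. Barcodes held 104 to 906 UMIs in IM15 and 111 to 988 in IM17. Intervals of levels are exact Poisson, those of shares exact binomial (Clopper-Pearson), and those of ratios exact conditional binomial, all at 95%.

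The tests, the 30 gene lists with 257 entries, the rule for named genes and a set of alternative settings were chosen before the data were examined, and several had to change because of what the matrices hold. Numerical bounds not named as planned below, such as those on list members, class genes, pseudocount and co-variation, were set after the matrices were seen. The planned minimum of 1000 UMIs per barcode would have left 0 barcodes, so all deposited barcodes were used. The planned mitochondrial filter had no genes to work on. The planned thinning depths of 2000, 1000 and 500 UMIs were replaced by 200, which 7520 (81.3%) and 4498 (83.1%) of the barcodes reach. The planned class boundary of 3 list UMIs was lowered to 2, and the planned ranking of barcodes by a list score, tied at 0 for most, was replaced by the same boundary. Count-model tests with their own gene filter were planned, but tests were kept on the log2 scale of the deposited values, with limma on log2(CPM + 20) and a bound on mean CPM, a choice that the recovered UMIs did not force. List UMIs stand in for the planned z-scored list scores in co-variation. Scrublet called 0 doublets in either library, which is read as a method without power at this depth, so doublets were left untreated. Of the list genes, 20 are not among the deposited symbols and were not used here, Muc5ac, Epcam, Atp4b and Cdx1 among them.

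Levels are the UMIs of a gene or list as CPM of the library, given as mean and SD of the 2 libraries. The library difference is the log2 ratio of IM17 over IM15 for genes of mean 50 CPM or more, where a gene counted as apart when the ratio and its whole interval lay beyond 2-fold. List medians use members of mean 10 CPM or more and are placed among 10000 random lists matched on mean expression in 20 bins. Background, a measure added after the data were seen, is the 95th percentile of 327 olfactory and 74 vomeronasal receptor genes per library. A gene was called partner-dependent, also a measure added afterwards, when in both libraries its CPM was at least 4-fold lower in barcodes without a given abundant gene than in barcodes with it. Genes of 100 UMIs or more were examined against 208 abundant genes, and 211 of 7932 were dependent, with 4.38% of all UMIs.

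For clusters, counts were scaled to 10000 per barcode and log-transformed, 2000 variable genes were chosen within library, of which 1994 remained without ribosomal protein genes, and Leiden clustering (leidenalg on 15 neighbours in 30 components, resolution 0.5) was run on both libraries together. Each cluster was searched for cell type list members among its 10 most raised genes.

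For the class comparisons, barcodes were thinned to 200 UMIs and called positive or high with at least 2 UMIs of the G2/M, SPEM or foveolar list, and negative or low with 0. UMIs were summed per class and library into 4 sums, genes of mean 100 CPM or more outside the list were kept, and limma with a mean-variance trend was fitted with library as a block, leaving 1 residual degree of freedom, with Benjamini-Hochberg adjustment at 0.05. The prior degrees of freedom were infinite for the G2/M and SPEM fits and 33.7 for the foveolar fit. SEs and p-values therefore rest almost wholly on variance shared across genes, not on a gene's own spread between libraries. Lists with at least 3 tested genes were tested with camera (preset correlation 0.01, and estimated) and fry. The fit was tested on simulated Poisson sums with 200 genes changed 4-fold, 2-fold, 0.5-fold or 0.25-fold. Of unchanged genes it called 8 of 1454 (G2/M), 8 of 1374 (SPEM) and 8 of 1450 (foveolar). Only genes that passed the bound on mean CPM were counted. That left 28, 27 and 27 genes lowered to 0.25-fold, against 50 raised 4-fold in each comparison. Of those lowered genes 64.3%, 100% and 66.7% were recovered, so recovery over all lowered genes was smaller.

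Co-occurrence, a measure added after the data were seen, counts the pairs of different list genes that meet in a barcode of 200 UMIs and divides by the count expected from each gene's share of barcodes, leaving out partner-dependent genes. List co-variation is the Spearman correlation of list UMIs across barcodes for lists of at least 200 CPM, read against 20 shuffles of UMIs over barcodes.

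Named genes follow the rule set at the start: members of the cell type and dysplasia-associated lists and the 20 most abundant genes outside ribosomal protein genes for levels, the 12 highest and 12 lowest ratios for the library difference, and genes past the threshold in the same direction in both libraries, or members of any list, for the class comparisons. Members of the other lists named for levels or ratios, the sex-linked genes and Kras were chosen after their values were seen. Alternatives covered scaling, gene and barcode filters, the weight of a barcode, pseudocounts, thinning depth, class boundaries, the library block, clustering settings and the left-out library. Tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 and limma 3.58.1 in R 4.3.3.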

Results

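Single-cell RNA sequencing was collected from metaplastic organoids of the mouse stomach. The organoids are gastroids, gastric epithelium grown in culture, taken from mice of the Mist1-Kras line at 1 month past induction. In these mice an active form of Kras, a growth-signalling GTPase, is switched on in chief cells, the zymogen-secreting cells at the base of the gastric gland. Cells were captured with inDrop, a droplet method that tags the RNA of each droplet with a cell barcode and each molecule with a unique molecular identifier (UMI). The labels give a single group, Meta1 metaplastic organoids, with 2 libraries, replicate 1 (IM15) and replicate 2 (IM17), and they do not say what the IM number stands for. The series design also names dysplastic organoids, whose libraries were not analysed here, so levels and the spread between the 2 libraries are described and no group comparison was made. IM15 held 9251 barcodes and 3010995 UMIs, with a median of 302 UMIs and 236 genes per barcode. IM17 held 5411 barcodes and 1788142 UMIs, with a median of 295 UMIs and 214 genes per barcode. The deepest barcode held 906 UMIs in IM15 and 988 in IM17, so single barcodes were shallow and library sums carry most of the precision. All intervals below are 95% intervals and cover counting error only.

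The first question was which gastric programs the metaplastic organoids expressed. Summed over the genes that are listed, the mucous neck and SPEM list was the highest of the gastric lineage lists, though the foveolar, chief and parietal lists each lack 1 gene. SPEM is spasmolytic polypeptide-expressing metaplasia, a mucous lineage that appears in the injured gastric corpus. Its 8 genes summed to 2831 ± 831 UMIs per 1000000 (CPM; mean ± SD, n = 2 libraries), and all 8 members lay above background in both libraries. The chief cell list stood at 944 ± 461 CPM and the surface mucous (foveolar) list at 919.5 ± 366 CPM. The 4 measured pan-epithelial genes summed to 3330.2 ± 528 CPM, while fibroblast, immune, endothelial and erythroid lists each stood below 100 CPM. Background was read from 401 olfactory and vomeronasal receptor genes, which gastric epithelium has no known use for. Their median was 3.65 CPM in IM15 and 2.24 CPM in IM17, and a gene was taken to be above background when it passed their 95th percentile, 15.6 and 11.2 CPM.

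Within the SPEM list, Wfdc2, a secreted protease inhibitor, stood at 912 ± 291 CPM, the adhesion receptor Cd44 at 779 ± 114 CPM and the water channel Aqp5 at 583 ± 296 CPM (n = 2 for each). Slc7a11, a cystine transporter, stood at 148 ± 32.8 CPM. Tff2, the spasmolytic polypeptide itself, stood at 131 ± 165 CPM, a spread larger than its mean, since IM15 held 247 CPM and IM17 14.5 CPM. The mucin Muc6 stood at 60.7 ± 22.6 CPM and Gkn3 at 120.0 ± 49.4 CPM. In the GRCm38 annotation Wfdc2 lies on chromosome 2 (164562413 to 164568510, plus strand) and Tff2 on chromosome 17 (31141049 to 31144282, minus strand).

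Of the chief cell list, Gif, which encodes gastric intrinsic factor (chromosome 19, 11747554 to 11763447, plus strand), stood at 829 ± 393 CPM and Pgc, a pepsinogen, at 99.9 ± 65.4 CPM (n = 2). Those were the 2 of 5 measured chief cell genes above background in both libraries. Of the foveolar list, 3 of 6 measured genes lay above background in both libraries. They were the aspartic protease Ctse at 621 ± 217 CPM, the trefoil peptide Tff1 at 162 ± 131 CPM and the surface protein Psca at 109.9 ± 5.18 CPM. Gkn1 and Gkn2, abundant pit cell products of the normal stomach, stood at 9.18 ± 1.11 and 2.55 ± 2.03 CPM, below background. Muc5ac, the main surface mucin, was not used here because the deposited gene list lacks it. Parietal cell genes summed to 199.9 ± 35.2 CPM, of which the potassium channel Kcnq1 gave 135 ± 40.6 CPM, while Atp4a, a subunit of the gastric proton pump, stood at 3.95 CPM on average.

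The intestinal, goblet, endocrine, tuft, squamous and stromal lists all stood below the foveolar list. The intestinal list summed to 443 ± 68.4 CPM, and 3 of its 11 measured genes lay above background in both libraries. Cdx2, the intestinal master regulator, stood at 2.00 ± 0.458 CPM, below background, and the enterocyte cadherin Cdh17 at 10.8 ± 3.46 CPM. The goblet list summed to 143 ± 64.7 CPM, with Tff3 at 81.2 ± 39.7 CPM and the mucin Muc2 at 26.6 ± 18.7 CPM. Muc2 was at least 4-fold lower in barcodes without the metallothionein Mt1, so its level is uncertain. Endocrine genes summed to 84.5 ± 54.7 CPM (2 of 8 above background in both libraries, with Hdc at 49.3 CPM uncertain because it depended on Cystm1 in the same way), tuft cell genes to 114 ± 16.4 CPM (1 of 7) and squamous genes to 58.4 ± 22.6 CPM (2 of 6). The fibroblast list stood at 57.5 ± 17.3 CPM, the immune list at 83.8 ± 14.9 CPM, the endothelial list at 40.7 CPM and the 1 measured erythroid gene at 7.49 ± 5.85 CPM. Above background in both libraries were 1 of 6 fibroblast, 2 of 5 immune, 0 of 4 endothelial and 0 of 1 erythroid genes.

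The dysplasia-associated list stood at 1247 ± 39.5 CPM, with 6 of 8 genes above background in both libraries. Prom1, a surface marker used for stem-like cells, stood at 359 ± 54.5 CPM, the progenitor transcription factor Sox9 at 287 ± 8.70 CPM, the adhesion molecule Alcam at 242 ± 0.422 CPM and the claudin Cldn7 at 186 ± 2.53 CPM. Tacstd2, which encodes the surface protein Trop2, stood at 44.4 ± 21.9 CPM, and the secreted Mmp7 and Lcn2 at 3.67 ± 0.445 and 8.80 ± 2.58 CPM, below background. These are levels in metaplastic organoids alone, and the dysplastic counterpart was not analysed here.

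The most abundant transcript outside the ribosomal protein genes was Sprr2a2, a small proline-rich protein of cornified and injured epithelium (chromosome 3, 92215920 to 92256724, plus strand), at 39868 ± 3015 CPM. Sprr2a2 belongs to a family of near-identical copies, and how shared reads were counted is not given, so the value is uncertain as to the copy. Clu, which encodes clusterin and marks regenerating epithelium, followed at 6668 ± 1402 CPM (chromosome 14, 65968483 to 65981547, plus strand). The calcium-binding S100a6 stood at 3882 ± 1502 CPM, the metallothioneins Mt1 and Mt2 at 2438 ± 341 and 1817 ± 611 CPM, and the cyclin Ccnd2 at 1928 ± 389 CPM. With Clu and S100a6, the YAP and regenerative list was the highest of the state lists outside ribosomal protein genes at 13263 ± 2441 CPM. Its member Ly6a, at 1812 ± 594 CPM, was at least 4-fold lower in barcodes without Gm29123, so that part of the sum is uncertain. Gm17541, Wdr24 and Nfatc2 also ranked among the 20 most abundant, but each was at least 4-fold lower in barcodes without a given ribosomal protein transcript, so how far they reflect expression is uncertain. The ribosomal protein genes summed to 153864 ± 1012 CPM.

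Among the other state lists, hypoxia and glycolysis genes summed to 3743 ± 435 CPM, ERK output genes to 1800.4 ± 131 CPM, unfolded protein response genes to 1227 ± 199.6 CPM and cholesterol synthesis genes to 1188 ± 513 CPM. NRF2 targets, which answer oxidative stress, summed to 642 ± 149 CPM, immediate early genes to 658 ± 148 CPM, MHC class I genes to 484 ± 1.84 CPM, stem and Wnt genes to 405 ± 3.49 CPM, gastric transcription factors to 329.9 ± 40.5 CPM and EGFR ligands to 248 ± 46.4 CPM. All 7 gastric transcription factors lay above background in both libraries, and so did 8 of 9 stem and Wnt genes, 9 of 11 ERK output genes, 4 of 5 EGFR ligands and all 10 cholesterol synthesis genes. Interferon response genes summed to 135 ± 34.9 CPM with 2 of 8 above background in both libraries, and the 1 measured MHC class II gene, Cd74, stood at 3.05 ± 2.73 CPM. G2/M phase genes summed to 939 ± 492 CPM and S phase genes to 856 ± 286 CPM.

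**Figure D1:**
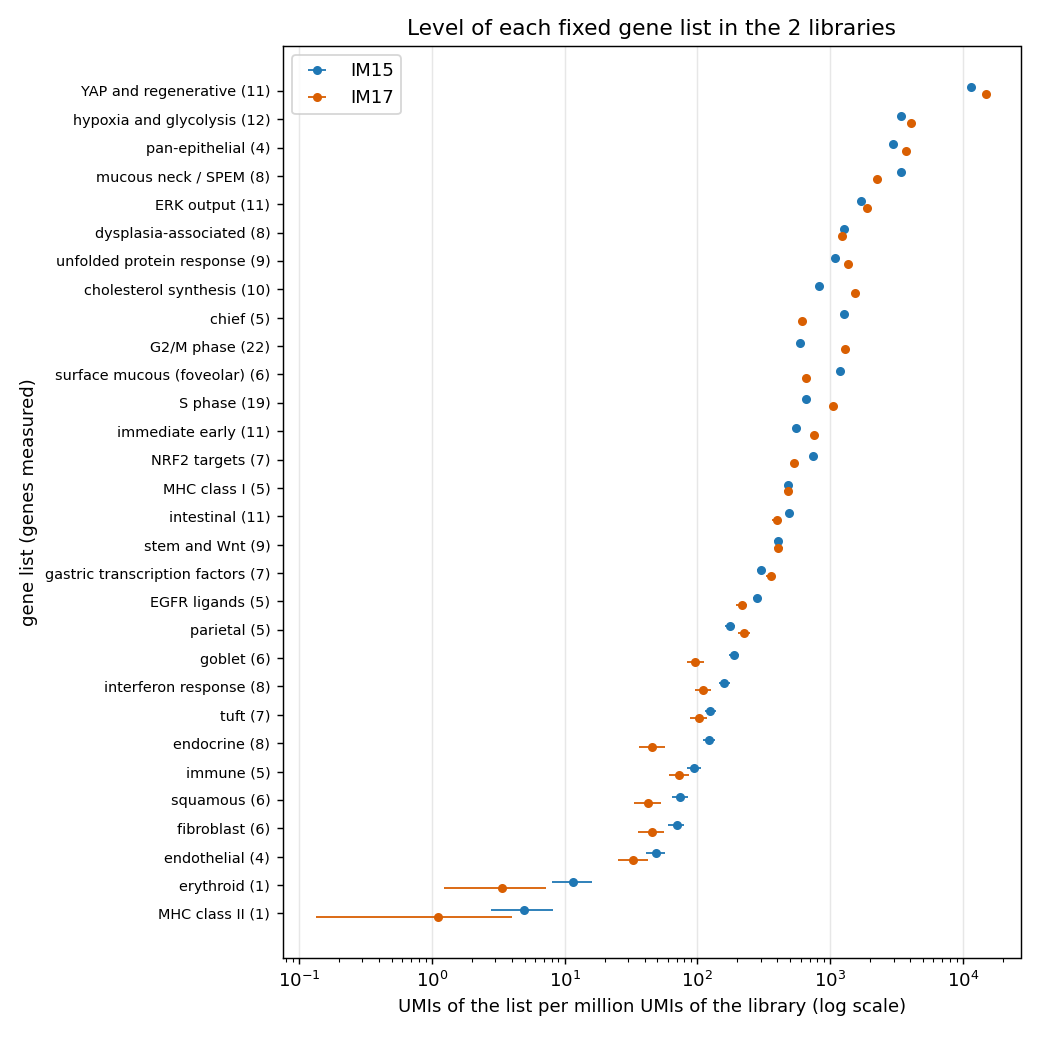
Level of each fixed gene list, as CPM on a log axis, with IM15 in blue and IM17 in orange, and bars giving 95% Poisson intervals of counting error. The YAP and regenerative list tops the plot at 11537 CPM in IM15 and 14989 CPM in IM17, and the SPEM list stands at 3418 and 2243 CPM.

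The next comparison set the 2 libraries of the group side by side, which measures how far replicate organoid libraries differed. IM17 held more proliferation and sterol synthesis transcripts, and IM15 held more mucous transcripts and more of the chief cell transcripts Gif and Pgc. The G2/M list stood at 1287 CPM in IM17 and 591 CPM in IM15, 2.18-fold higher in IM17, and the cholesterol synthesis list was 1.88-fold higher in IM17. The SPEM list was 1.52-fold, the foveolar list 1.78-fold and the chief cell list 2.05-fold higher in IM15. With 1 library on each side there is no replicate check and no p-value, so these are differences between these libraries.

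Cell cycle genes moved as a group. Of the 21 G2/M genes of mean 10 CPM or more, 19 were higher in IM17, and their median log2 ratio of IM17 over IM15 was 1.19. That lay above all of 10000 random lists matched on expression, whose central 95% ran from -0.38 to 0.30. Ube2c, a mitotic ubiquitin-conjugating enzyme, stood at 59.4 CPM in IM15 and 166 CPM in IM17, the mitotic kinase Cdk1 at 40.9 and 112 CPM, Birc5 (survivin) at 25.9 and 72.7 CPM, and the topoisomerase Top2a at 75.1 and 135 CPM. The 2 exceptions were higher in IM15, among them Cenpf at 14.9 and 12.9 CPM. S phase genes had a median log2 ratio of 0.61, also at the 100th percentile of the random lists, with 16 of 19 genes higher in IM17. Rrm2, a ribonucleotide reductase subunit, was 2.92-fold higher in IM17 and the histone gene Hist1h2ap 4.71-fold.

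All 10 cholesterol synthesis genes were higher in IM17, with a median log2 ratio of 0.98 at the 100th percentile. Hmgcs1, an early enzyme of the mevalonate pathway, stood at 105 CPM in IM15 and 242 CPM in IM17, Idi1 at 105 and 258 CPM, and the LDL receptor gene Ldlr at 51.1 and 133 CPM. The fatty acid desaturases Scd1 and Scd2 were among the 12 highest ratios, at 3.11-fold and 3.06-fold, and Scd2 stood at 726 CPM in IM15 and 2226 CPM in IM17. Immediate early genes had a median log2 ratio of 0.54 (percentile 99.4, 9 of 11 higher in IM17). The unfolded protein response list (0.37, percentile 91.5) and the pan-epithelial list (0.53, percentile 92.5) lay inside the central 95% of random lists.

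Mucous genes went the other way. The foveolar list had a median log2 ratio of -0.99 (percentile 1.09, 0 of 4 genes higher in IM17) and the SPEM list -0.56 (percentile 0.690, 2 of 8 higher in IM17). The foveolar median leans on Dpcr1, at 21.3 CPM in IM15 and 8.95 CPM in IM17, the latter below background. Over the 3 foveolar genes without it the median was -0.73, and no random lists were drawn for that set. Psca was near equal, at 114 and 106 CPM. Tff2 was 17.0-fold higher in IM15, Tff1 3.70-fold, Ctse 1.66-fold, Wfdc2 1.58-fold and Aqp5 2.12-fold, whereas Gkn3 and Glipr1 were the 2 SPEM genes higher in IM17, at 1.82-fold and 1.86-fold. Of the chief cell genes Gif was 2.01-fold and Pgc 2.72-fold higher in IM15. The goblet list had a median of -1.31 (percentile 0.470, 4 genes), but without the partner-dependent Muc2 it was -1.04 (percentile 6.86, 3 genes), inside the central 95%. NRF2 targets had a median of -0.55 at the edge of the central 95% (percentile 2.44, and 2.56 in a second draw of random lists), and the quinone reductase Nqo1 stood at 46.2 CPM in IM15 and 1.12 CPM in IM17, or 2 UMIs. Interferon response (-0.88, percentile 3.21) and squamous genes (-0.90, percentile 10.3) lay inside the central 95%.

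Other lists were near balance by their medians. Median log2 ratios were 0.02 for the dysplasia-associated list (percentile 26.7), 0.12 for gastric transcription factors (59.4), 0.28 for hypoxia and glycolysis (76.2), -0.29 for EGFR ligands (22.9), -0.33 for the intestinal list (14.4) and -0.37 for tuft cell genes (41.8). Stem and Wnt (-0.04, percentile 45.2), ERK output (-0.14, percentile 33.7), YAP and regenerative (-0.08, percentile 24.2) and MHC class I genes (-0.09, percentile 33.0) change sign under other scalings of the libraries. The sum of the YAP and regenerative list was 1.30-fold higher in IM17 (14989 against 11537 CPM), though 6 of its 10 genes were higher in IM15. The 91 ribosomal protein genes of mean 10 CPM or more had a median of 0.00, at percentile 1.41 of random lists whose central 95% ran from 0.01 to 0.27. Chief, parietal, endocrine, fibroblast, immune and endothelial lists had too few genes of mean 10 CPM or more for a median.

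Gene by gene, 36 of 3654 genes of mean 50 CPM or more were at least 2-fold higher in IM17 and 164 at least 2-fold higher in IM15, with the whole counting interval beyond 2-fold. This split follows the scaling. With TMM it was 113 and 85 genes, and with a median ratio size factor 116 and 83. The tested genes had a median log2 ratio of 0.17 under scaling to total UMIs, and TMM and the median ratio subtracted a shift of -0.24 and -0.25 from every ratio. The directions of the G2/M, S phase, cholesterol synthesis, SPEM and foveolar medians held under each. A random split of the barcodes within a library gave 0 such genes in IM15 and 1 in IM17. Such a split holds counting noise alone and cannot show the spread between replicate cultures. Of the 164 genes, 42 depended on a partner transcript, against 0 of the 36. Among all genes of 100 UMIs or more the dependent share was 2.66% (211 of 7932). Over the 223 dependent pairs the median log2 ratio of IM17 over IM15 was -0.96 for the dependent gene and 0.16 for its partner. How far those 42 genes reflect expression is therefore uncertain. With dependent genes left out, 37 genes were higher in IM17 and 130 in IM15.

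The most uneven gene was Xist, the noncoding RNA of X inactivation (chromosome X, 103460366 to 103483254, minus strand), at 2324 CPM in IM15 and 44.7 CPM in IM17, 52.0-fold higher in IM15. Dmbt1, a secreted mucosal defence glycoprotein, followed, then Spag11b, both with IM17 levels below background (7 and 8 UMIs), so their folds of 27.7 and 21.9 are rough. Next came Tff2, the muscle cytochrome oxidase subunit Cox6a2 at 16.1-fold and Adrbk2 at 11.5-fold. Zfp418 (8.28-fold, partner-dependent), Gm26691, the growth factor binding protein Igfbp4 (7.29-fold), Cyp2c70, Evx1os and Ccdc36 (6.67-fold) completed the 12 lowest ratios. The highest ratios belonged to Tnfrsf13c at 6.17-fold higher in IM17 and the matrix glycoprotein Thbs1 at 5.82-fold. They were followed by Hist1h2ap, the ketone body enzyme Oxct1 (3.59-fold), Zdbf2 (3.15-fold), Scd1, Scd2, Capn6 (3.02-fold), Sptssb (2.96-fold), Rrm2, the cytoskeletal actin Actg1 (2.81-fold) and the translation factor Eif5a (2.81-fold). Across the 3654 genes, which are not independent replicates, log2 levels of the libraries correlated at Pearson r = 0.850 and Spearman rho = 0.694.

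**Figure D2:**
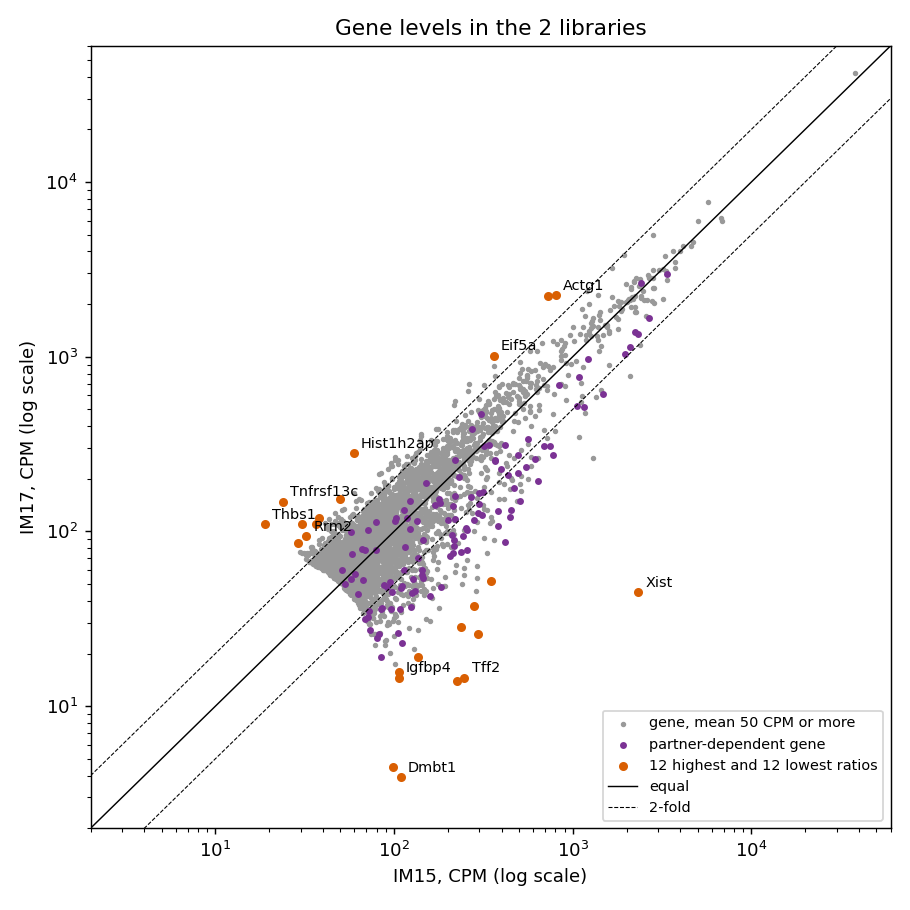
CPM of each gene in IM15 (horizontal) and IM17 (vertical), both on log axes, for the 3654 genes of mean 50 CPM or more. Purple points are partner-dependent genes, orange points the 12 highest and 12 lowest ratios, and the dashed lines mark 2-fold; Xist stands far to the right at 2324 against 44.7 CPM.

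**Figure D3:**
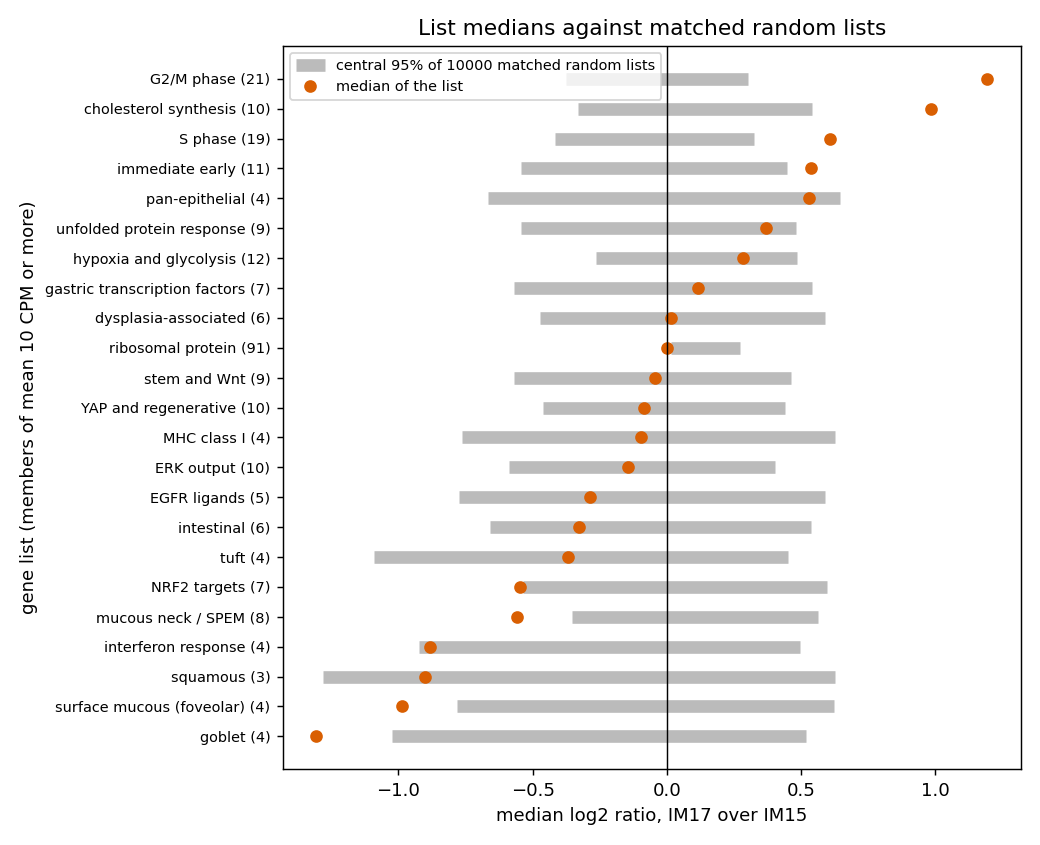
Median log2 ratio of IM17 over IM15 for each list (orange points) on the central 95% of 10000 random lists matched on expression (grey bars). G2/M phase (1.19), cholesterol synthesis (0.98) and S phase (0.61) lie right of their bars, and the foveolar (-0.99) and SPEM (-0.56) medians lie left of theirs. The goblet median (-1.31) does so only with the partner-dependent Muc2 counted. The foveolar median counts Dpcr1, which lay below background in IM17.

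The remaining comparisons asked whether these programs sat in distinct cells. In neither library did the genes of a program gather in the same barcodes beyond what independent draws would give. With each barcode thinned to 200 UMIs, different G2/M genes met in a barcode 50 times in IM15 against 42.2 expected, a ratio of 1.18 (0.879 to 1.56), and 112 times in IM17 against 99.6, a ratio of 1.12 (0.926 to 1.35). SPEM genes gave 0.984 (0.922 to 1.05) and 0.945 (0.823 to 1.08), and pan-epithelial genes 0.990 and 1.07. Of the lists with at least 10 expected pairs, 0 of 19 in IM15 and 0 of 14 in IM17 had a lower bound above 1. The excess that these intervals leave room for was below 2-fold for G2/M genes in both libraries. The intervals treat pairs as independent, although a barcode with several list genes gives several pairs, so they may be too narrow.

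**Figure D4:**
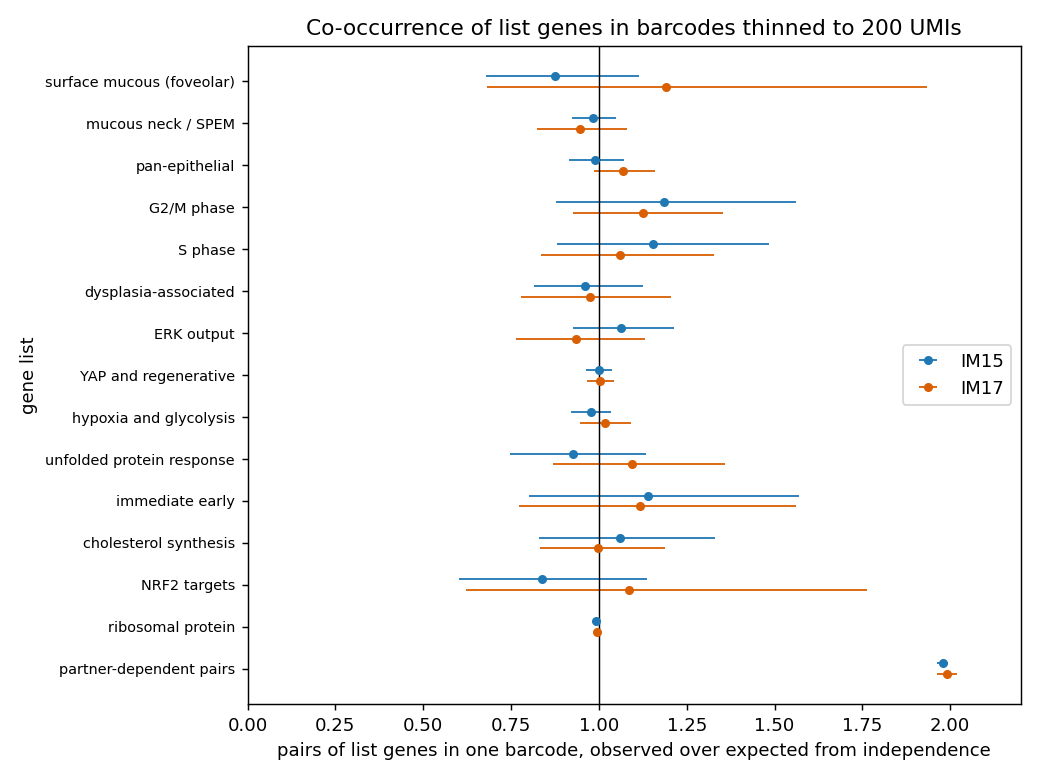
Observed over expected number of barcodes in which different genes of a list meet, at 200 UMIs per barcode, with 95% Poisson intervals, for lists with at least 10 expected pairs in both libraries. List ratios sit near 1, with G2/M phase at 1.18 in IM15 and 1.12 in IM17, while partner-dependent pairs, which were selected for meeting in barcodes, sit at 1.98 and 1.99.

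Clustering did not give named cell populations. Leiden clustering of the 14662 barcodes gave 4 clusters, and 0 of the 4 had a cell type marker among its 10 most raised genes. The clusters followed the presence of 2 abundant transcripts, S100a6 and the cyclophilin Ppia. In cluster 1, 99.4% of barcodes held S100a6 and 80.0% held Ppia. In cluster 2 the shares were 0.118% and 0.283%, in cluster 3 99.97% and 0.181%, and in cluster 4 0.118% and 100%. Cluster 1, where Scd2 was also high, took 22.6% (21.8 to 23.5, exact binomial) of IM15 and 45.6% (44.3 to 47.0) of IM17 barcodes. Cluster 2, where Xist and Cox6a2 were high, took 34.9% (34.0 to 35.9) and 18.7% (17.7 to 19.8). Of its barcodes 76.2% came from IM15, the library in which both genes were higher, so their rise there goes with library make-up. Clusters 3 and 4 took 25.4% and 17.0% of IM15 and 17.9% and 17.8% of IM17. The number of clusters ran from 2 to 9 over the other settings tried, and the partition did not recur in several of them (adjusted Rand index of 0.155 with 1000 and 0.00883 with 4000 variable genes), so these shares describe 1 partition among several.

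Barcodes with at least 2 G2/M UMIs after thinning to 200 numbered 102 of 7520 in IM15, 1.36% (1.11 to 1.64, exact binomial), and 216 of 4498 in IM17, 4.80% (4.20 to 5.47). The order follows the 2.18-fold difference of the G2/M list between the library sums. SPEM-list-high barcodes, by the same rule, made up 16.8% of IM15 and 9.20% (8.37 to 10.1) of IM17, and foveolar-list-high barcodes 4.11% (3.67 to 4.58) and 2.29% (1.87 to 2.77). No cluster could be named as a cell type that lacks these genes, so no background share stands beside these. They count barcodes with list UMIs, not cycling or metaplastic cells. The list UMIs of a barcode could also come from a single gene. Pairs of different list genes numbered 50 (IM15) and 112 (IM17) for G2/M, and 66 and 16 for the foveolar list. The foveolar-list-high barcodes numbered 309 and 103, so most were called on repeat UMIs of 1 gene. Many G2/M-positive barcodes were called in the same way. The class comparisons below share this limit.

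Each such class was set against the barcodes with 0 UMIs of its list in limma, on 4 class sums with library as a block, leaving the list's own genes out. G2/M-positive against G2/M-negative cells differed in 1 of 1645 genes. Bri3bp (chromosome 5, 125441568 to 125460370, plus strand) was higher in positive barcodes by 1.67 on the log2 scale (SE 0.39, adjusted p = 0.0309, limma with Benjamini-Hochberg), 2.00 in IM15 and 1.34 in IM17. In those barcodes it stood at 490 CPM of 20400 UMIs (IM15) and 255 CPM of 43200 UMIs (IM17), so both folds rest on few UMIs. Bri3bp transcripts share a 25-base word with 5 of the 22 G2/M genes, and Bri3bp met those 5 in 11 barcodes of IM15 against 12.3 expected and in 13 of IM17 against 10.8. It met the other 17 in 44 barcodes of IM15 against 30.4 expected and in 33 of IM17 against 26.3. At an unadjusted p under 0.05 there were 87 genes. SPEM-list-high against SPEM-list-low cells differed in 0 of 1593 genes by limma, with 70 at an unadjusted p under 0.05 and a lowest adjusted p of 0.539. Foveolar-list-high against foveolar-list-low cells differed in 1 of 1615 genes, with 93 at an unadjusted p under 0.05. G2e3, a ubiquitin ligase gene (chromosome 12, 51348061 to 51376986, plus strand), was higher by 1.94 (SE 0.40, adjusted p = 0.0473, limma), 2.74 in IM15 and 1.15 in IM17. The IM17 fold rests on few UMIs, as G2e3 stood at 146 CPM in a high class of 20600 UMIs. G2e3 met the foveolar gene Tff1 in 321 barcodes of IM15 against 31.4 expected, but the other abundant foveolar gene, Ctse, in 97 against 85.9.

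Fold changes of the 3 comparisons did not repeat between libraries. Across genes they correlated at -0.0342 for G2/M, -0.00206 for SPEM and 0.00228 for foveolar classes. Counting noise lowers such correlations, as the smallest sums held 20400 (G2/M), 82800 (SPEM) and 20600 (foveolar) UMIs. In simulated class sums of the same size, limma recovered 96.0% of genes raised 4-fold in the G2/M comparison, 100% in the SPEM comparison and 98.0% in the foveolar comparison, and 33.3%, 98.0% and 40.8% of genes raised 2-fold. The simulation held Poisson noise alone and the same fold in both libraries. UMIs across barcodes varied more than that, with a median variance over mean of 1.144 in IM15 and 1.28 in IM17, so recovery in these data may be lower. Neither call was stable. The Bri3bp call held with a pseudocount of 5 CPM and was lost under the other 9 alternatives, where the log2 difference stayed at 1.67 with other gene filters or no library block, but fell to 0.43 with a boundary of 1 UMI and turned to -0.34 with 3 UMIs. The G2e3 call held with unthinned counts and with a boundary of 1 UMI. It was lost under the other 8, with a log2 difference of 1.39 to 2.36 in 7 of them and 0.29 when thinned to 100 UMIs.

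Gene list tests gave no call. Of 9 lists tested for G2/M, 9 for SPEM and 10 for foveolar classes, camera called 0 with the preset correlation (lowest adjusted p = 0.125, 0.768 and 0.271) and 0 with an estimated correlation (lowest adjusted p = 0.796, 0.979 and 0.760), and fry also called 0. In G2/M-positive barcodes the 3 immediate early genes tested had a median log2 difference of 0.68 and the 6 YAP and regenerative genes -0.23 (adjusted p = 0.125 for each, camera with preset correlation; 0.796 with an estimated correlation). No list member passed over all genes tested. Adjusted over the list alone, 1 of 4 pan-epithelial, 1 of 6 YAP and regenerative and 1 of 77 ribosomal protein genes passed as lower in G2/M-positive barcodes, and 1 of 4 pan-epithelial genes as higher in foveolar-list-high barcodes. The pan-epithelial gene was the keratin Krt18 in both, at -0.57 (SE 0.22) and 0.44 (SE 0.16) on the log2 scale, and the YAP and regenerative gene was Clu at -0.27.

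List co-variation across cells was weak. Over 171 pairs of 19 lists the largest Spearman correlation of list UMIs across barcodes was 0.0424 in size. The same sign in both libraries was found for 91 pairs, close to what unrelated values would give. The pair of the foveolar and pan-epithelial lists, at 0.0248 in IM15 and 0.0170 in IM17, was the 1 pair above all 20 shuffles in both libraries, and 0 pairs lay below all of them in both. With only 20 shuffles and 171 pairs, 1 such pair may arise by chance. Barcodes are not replicates, so no p-value is given.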

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

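Alternatives with bounds of 200 or 300 UMIs per barcode, other pseudocounts, gene filters of 50 or 200 CPM or thinning to 100 UMIs in the class tests, boundaries of 1 or 3 UMIs, other depths for co-occurrence, and those leaving out partner-dependent genes, Sprr2a2 or the genes that split the clusters were chosen only after the data were seen. The others were planned. List levels moved beyond the SD of the 2 libraries in 4 of 124 alternatives. Those that left out a library could not count as moved, since a single library always lies within that SD of the mean. List medians moved beyond the counting error of the list sums in 58 of 206, with 0 called medians turned in sign. The 20 and 100 CPM gene filters cannot move a list median, so these counts do not measure stability. Where a value below moved, the cause was not tested unless the alternative itself changes the genes or UMIs used. Planned runs on doublets, a mitochondrial filter, mitochondrial genes left out of the total, barcodes of at least 3000 UMIs, class tests with a boundary of 5 UMIs and top against bottom ranks of a score were not made, and running without a barcode filter equals the result as reported. Count-model alternatives were not run, since tests were kept on the log2 scale of the deposited values, a choice that the recovered UMIs did not force. Depth limits the results per barcode, as the shares below change with thinning. In simulated class sums with Poisson noise alone the fit recovered 33.3% (G2/M) and 40.8% (foveolar) of genes raised 2-fold.

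Genes at least 2-fold higher in IM17 numbered 113 (TMM), 116 (median ratio) and 67 (genes of mean 20 CPM or more), against 36 as reported. Those higher in IM15 numbered 85, 83 and 254, and 91 with genes of mean 100 CPM or more, against 164, where the gene filter changes how many are tested. These 5 list medians kept their sign. The foveolar median was -0.75 (TMM), -0.74 (median ratio), -0.86 (barcodes weighted equally) and -1.12 (300 UMIs or more), and the SPEM median -0.32, -0.31 and -0.47 (TMM, median ratio, 300 UMIs or more). The G2/M median was 1.43 (TMM), 1.44 (median ratio), 1.35 (equal weights) and 1.09 (200 UMIs or more). The S phase median was 0.85 and 0.86 (TMM, median ratio) and the cholesterol synthesis median 1.22, 1.23 and 1.06 (TMM, median ratio, 300 UMIs or more). Scaling and gene filters cannot move the percentile among random lists. Where barcodes were weighted equally or held to 200 or 300 UMIs, it was 100 for G2/M and cholesterol synthesis genes, and ran from 0.470 to 1.35 for SPEM and 0.640 to 1.72 for foveolar genes.

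The number of clusters was 2 at resolution 0.3, 7 at resolution 1.0, 9 with 1000 variable genes, 2 with 4000 variable genes and 2 with barcodes of 300 UMIs or more, against 4. The adjusted Rand index with the reported partition was 0.155 and 0.00883 with 1000 and 4000 variable genes, 0.0936 and 0.00410 for IM15 and IM17 alone, and 0.00672 without the splitting genes. G2/M-positive shares in IM15 were 0.454% thinned to 100 UMIs, 2.93% unthinned, and 10.3%, 0.160% and 0.0133% with at least 1, 3 and 5 UMIs. In IM17 they were 1.85%, 9.46%, 19.5%, 1.36% and 0.111%. The share was higher in IM17 in each.

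Genes changed between G2/M classes by limma numbered 2 with a pseudocount of 5 CPM, 0 with 100 CPM, 0 with no filter on low counts, 0 with genes of mean 50 CPM or more, 0 with 200 CPM or more, 0 with no replicate block, 0 with unthinned counts of the same cells and 3 with a boundary of 3 UMIs, against 1. The count for SPEM classes was 2 with unthinned counts of the same cells, against 0. For foveolar classes it was 0 with a pseudocount of 5 CPM, 0 with 100 CPM, 0 with no filter on low counts, 0 with genes of mean 50 CPM or more, 0 with no replicate block, 2 with unthinned counts of the same cells, 0 with a boundary of 3 UMIs and 4 thinned to 100 UMIs, against 1. At an unadjusted p under 0.05, the fits with no replicate block gave 13, 1 and 16 genes for the G2/M, SPEM and foveolar classes. List pairs beyond all shuffles numbered 2 thinned to 100 UMIs and 0 with Pearson correlation, against 1, and 13 to 21 when a single library had to show it. That is a weaker demand, which chance meets more often.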

Other observations

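Apart from TMM scaling, which was planned, the tests in this part were chosen only after the result was seen. Some sex-linked genes differed between the libraries. Xist stood at 2324 CPM in IM15 and 44.7 CPM in IM17, and its antisense gene Tsix at 49.2 and 17.3 CPM. The Y-linked translation factor gene Eif2s3y stood at 11.3 CPM in IM15 and 60.4 CPM in IM17, a log2 ratio of 2.42 (1.85 to 3.02). Its IM15 level lay below the background of 15.6 CPM, so the ratio is rough. The Y-linked genes Ddx3y (25.6 and 30.2 CPM) and Kdm5d (49.8 and 45.9 CPM) had ratios whose intervals include 0 on the log2 scale, and Uty (39.5 and 24.6 CPM) was higher in IM15. Kras, the gene the mouse line is named for, stood at 54.1 CPM (46.1 to 63.1) in IM15 and 71.0 CPM (59.2 to 84.5) in IM17, and the counts do not tell the active allele from the normal one.

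Glutathione and redox genes of the NRF2 list were higher in IM15 in 5 of 7 cases. Gclm, a subunit of the glutathione-making ligase, stood at 219.5 CPM in IM15 and 150.4 CPM in IM17, its partner subunit Gclc at 151 and 87.2 CPM, and the heme oxygenase Hmox1 at 142 and 88.4 CPM, while the glutathione reductase Gsr stood at 92.0 and 120.2 CPM. The EGFR ligand Areg stood at 137.5 CPM in IM15 and 90.6 CPM in IM17. The chaperone Hspa5 stood at 386 CPM in IM15 and 674 CPM in IM17, and Ldha, the last enzyme of anaerobic glycolysis, at 902 and 1203 CPM. The gastric identity factor Foxa1 stood at 33.9 CPM in IM15 and 74.9 CPM in IM17. Within the intestinal list the galectin Lgals4 was higher in IM17 by a log2 ratio of 2.17 (1.60 to 2.76), while Dmbt1 stood at 109 CPM in IM15 and 3.91 CPM in IM17. Same-gene UMI pairs within barcodes exceeded the number from independent draws 1.38-fold in IM15 and 1.57-fold in IM17, and 1.98-fold and 2.60-fold with the most abundant gene, Sprr2a2, left out.

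Genes of a program, cell cycle genes included, met in a barcode about as often as independent draws would give, with a ratio for G2/M genes of 1.18 in IM15 and 1.12 in IM17. Independent draws from a common RNA pool alone are argued against, since the median variance over mean of a gene's UMIs across barcodes was 1.144 in IM15 and 1.28 in IM17, against at most 0.998 and 0.993 in 20 simulated pools. Too few UMIs to see any co-occurrence is argued against for an excess of 2-fold or more, since the upper bounds were 1.562 (IM15) and 1.353 (IM17), and a smaller excess stays open. Those bounds treat pairs within a barcode as independent and may be too low. A common pool whose molecules were counted more than once, a culture of cells that are alike at this depth, or barcodes shared by several cells stay open and were not tested. The design holds a single group, so no biological explanation was tested.

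Partner-dependent genes were at least 4-fold lower in barcodes without a given abundant transcript, in 223 pairs with 95 partners, 33 of them ribosomal protein genes. Both transcripts of a pair shared a 25-base word on the same strand in 11.16% of 215 pairs with sequence, against at most 1.86% when pairs were shuffled, so reads of the abundant transcript assigned to a gene with shared sequence may account for part of the pairs. Long shared sequence behind all of the pairs is argued against, as the upper bound of that share was 16.15%. Words of 14 bases were shared in 41.9% of pairs against 10.1% on average when shuffled, while G2e3 and Tff1, which met in 321 barcodes of IM15 against 31.4 expected, shared neither length. No biological explanation was tested, and what ties the other pairs stays open.

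Proliferation and sterol genes were higher in IM17, and most mucous genes in IM15. Scaling between the libraries is argued against as the whole cause, since it moves every log2 ratio by the same amount. No such shift brings a foveolar median of -0.99 and a G2/M median of 1.19 both to 0. Under TMM they were -0.7509 and 1.431, which follows from its shift of -0.24 and is no separate test. More diffuse background in IM15, where receptor genes took 0.252% of UMIs against 0.156%, is argued against as the whole cause of the higher SPEM genes, but only for background of that size. With that background subtracted the SPEM median stayed at -0.5589 (8 genes). The 15.6 CPM (IM15) and 11.2 CPM (IM17) subtracted were small beside most SPEM genes, at 60.7 to 912 CPM on average, and could hardly move the median. Receptor genes cannot show background made of the organoids' own mucous transcripts, so that was not tested. The labels give neither a batch nor what sets IM15 apart from IM17, so a difference between cultures, animals or library preparations may lie behind the pattern and stays untested, as no biological explanation was tested.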
